A study of Mus musculus with 47 samples.

How the data were processed

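RNA sequencing was available for 29 mouse libraries in 7 groups: normal pro/pre-B cells (3 libraries), pre-tumour EuMyc cells with WT (5) or Het (5) Tfap4 genotype, and tumours labelled WT (4), Het (5), LOH (5) and KO (2). Groups were taken from the genotype and cell type labels, and what LOH stands for was not spelled out there. Each library carried a number of its own in the labels, and the series describes the libraries of a group as biological replicates. Another 18 libraries, 6 groups of 3, came from chromatin immunoprecipitation and its inputs and were not analysed here.

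Per the labels' protocols, cells were sorted on an Aria-II, total RNA was extracted with Trizol, ribosomal RNA was depleted by hybridisation, cDNA was primed with random hexamers, and single reads of 50 bases were sequenced on a HiSeq2500 or HiSeq3000. Which instrument read which library was not given in the sources used here. The values analysed were gene-level RPKM as deposited by the authors, that is, reads scaled by gene length and by library size. Per the submitters' processing notes, STAR, Bowtie2 and HOMER were used with the builds mm10 and mm9. Which tool and build served the RNA libraries, how reads of near-identical genes were assigned and whether counting used strand were not given in the sources used here. Genes with near-identical copies, such as the immunoglobulin constant regions, the class I genes of the H2-Q family and the Vpreb genes, were therefore read as uncertain. The deposited table held no counts.

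The table had 41264 lines. After 574 repeated lines of the same identifier were dropped, 40690 gene identifiers remained, of which 40254 were found in the list of gene names. Where a symbol had several lines the one with the highest mean over the RNA libraries was kept, which left 40591 symbols. A table of RefSeq genes on the assembly GRCm38.p6 was used only to find which genes neighbour each other, and no coordinates are given. Relative depth was recovered from low values, which step by the worth of a single read. Between 97.9% and 99.3% of the ratios of low values (under 0.1 RPKM) in a library were whole-number ratios within a tolerance of 0.01, against at most 8.90% when a wrong step was used. On a scale with a middle near 1, relative depth ran from 0.777 to 1.55, and it limits the precision of genes with few reads. The absolute number of reads was not recovered, and no count-based test was run.

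Values were tested as log2(RPKM + 1). A fold change is on the log2(RPKM + 1) scale wherever a log2 change is given, which understates the change of low genes. Ratios given as fold are ratios of mean RPKM. Genes were tested with limma (lmFit and eBayes with trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05) if they reached an RPKM of 1 in at least as many libraries of the fit as its smallest group holds. The 13 non-tumour libraries, the 16 tumour libraries and the 19 libraries of WT and Het cells at both stages formed 3 fits, without covariates. The last of these also gave the interaction of stage and genotype. Levels of Tfap4 and Myc were compared by exact 2-sided permutation tests of the difference of mean log2(RPKM + 1), and for pre-tumour Het against WT cells also, added later, with labels exchanged only within each mouse number series. Errors are SD over libraries, or SE of a log2 change where stated.

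Before the data were examined, 20 gene lists, the comparisons, the tests and the rule for named genes were fixed. That rule took Tfap4 and Myc, the 10 called genes of largest rise and the 10 of largest fall with a mean of 2 RPKM or more in a group, and up to 4 called members of each list with the smallest p, without sex-linked transcripts, unnamed genes, antigen receptor segments and small non-coding genes listed by the start of their names. Mitochondrial transfer RNAs were not on that list, so mt-Tl1 stayed among the named genes. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A list with fewer than 3 measured members was counted and not tested. Members were also counted with p adjusted over the list alone. The markers of T, NK, myeloid, erythroid, plasmacytoid dendritic and plasma cells served as markers of other cells that a sort could hold, and the immediate-early list as a sign of handling.

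The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. Of these, 86 and 98 were recovered for pre-tumour WT against normal, with 4 false calls, and 91 and 100 for pre-tumour Het against pre-tumour WT, with 7. For tumour against pre-tumour cells, 74 and 94 were recovered in WT, with 12 false calls, and 78 and 96 in Het, with 10. For the interaction the numbers were 48 and 88, with 11 false calls. Against WT tumours, 53 and 96 were recovered for Het with 12 false calls, 50 and 86 for LOH with 7, and 28 and 84 for KO with 8. For LOH against Het tumours they were 50 and 91, with 8 false calls. Among tumours a change of 1 was thus recovered in 28 to 53 of 100 genes. The simulated values were independent between genes, with the same spread of a gene in all libraries of a fit and without library sets. They do not show recovery or false calls where tumours vary more than pre-tumour cells or where library sets differ.

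Alternatives covered the pseudocount (0.1), no filter on low values, median-of-ratios rescaling, quantile normalization, all 29 libraries in a single fit, library weights, a minimum log2 change of 1, the number series of the labels, the sort, and leaving out each library in turn. A term for the library set and a fit of 1 library set were added after the data were seen. Library sets were read from the values: a library with more than 3000 of the 4918 listed processed pseudogenes at 0 was put in set C, and of the rest a library with more than 500 RPKM of Gm10800 in set B and the others in set A. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.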

Results

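RNA was measured in 29 libraries of sorted mouse B-lineage cells to follow the EuMyc transgene, which drives Myc from an immunoglobulin heavy-chain enhancer, and the loss of Tfap4, which encodes the helix-loop-helix transcription factor AP4. Normal pro/pre-B cells of bone marrow (3 libraries), pre-tumour EuMyc cells taken at 3 to 4 weeks of age with WT (5) or Het (5) Tfap4 genotype, and tumours labelled WT (4), Het (5), LOH (5) and KO (2) were compared. Each library had its own number, and the series calls the libraries of a group biological replicates. Relative depth was 0.882 to 1.14 in normal, 1.04 to 1.43 in pre-tumour WT and 0.859 to 1.14 in pre-tumour Het libraries. In tumours it was 0.830 to 0.969 in WT, 0.777 to 1.55 in Het, 0.847 to 1.06 in LOH and 0.822 to 0.853 in KO. All non-tumour cells and 8 tumours were sorted as B220+IgM-, while 2 WT, 3 Het and 3 LOH tumours were sorted on B220 alone. The values themselves put the libraries into 3 sets, A, B and C, by the number of processed pseudogenes listed at 0 (2628 to 2832 in 9 libraries, 1940 to 2618 in 9 and 3456 to 3530 in 11) and the level of the transcript Gm10800. Set C held only tumours (3 WT, 3 Het, 3 LOH and 2 KO), set B held all normal, 3 pre-tumour WT, 2 pre-tumour Het and 1 Het tumour library, and set A held 2 pre-tumour WT, 3 pre-tumour Het, 1 WT, 1 Het and 2 LOH libraries.

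Tfap4 was the targeted gene, and its deposited total was 3.50-fold higher in pre-tumour WT cells (40.6 ± 4.33 RPKM, SD, n = 5) than in normal cells (11.6 ± 0.658, n = 3; exact p = 0.0357, the smallest possible). In pre-tumour Het cells it was 35.2 ± 2.01 RPKM (n = 5), 0.867-fold of WT, and did not pass (exact p = 0.0556). Tumours had 37.2 ± 8.39 RPKM in WT (n = 4), 37.6 ± 4.41 in Het (n = 5), 45.9 ± 21.1 in LOH (n = 5) and 30.6 ± 4.02 in KO (n = 2). None of the tumour groups differed from WT tumours (exact p = 0.810 for Het, 0.571 for LOH and 0.533 for KO, where 0.133 was the smallest possible). Which part of Tfap4 was deleted is not known here, so a total over the gene does not test the genotype labels.

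Myc, the gene of the transgene, was 36.8-fold higher in pre-tumour WT (221 ± 56.3 RPKM, SD) than in normal cells (5.99 ± 1.42; n = 5 and 3, exact p = 0.0357). It was 273 ± 52.4 RPKM in pre-tumour Het cells (exact p = 0.159 against WT). With labels exchanged only within each of the 2 mouse number series, a test added after the values were seen, the log2 difference was 0.21 (exact p = 0.02, the smallest possible of 100 arrangements), and for Tfap4 it was -0.18 (exact p = 0.1). In tumours it was 223 ± 58.3 in WT, 206 ± 37.9 in Het, 403 ± 260 in LOH and 182 ± 2.82 in KO (n = 4, 5, 5 and 2), without a difference between tumours or between stages that passed (exact p = 0.0714 for LOH against Het and 0.0635 for Het tumours against pre-tumour Het). From WT pre-tumour cells to WT tumours neither Myc (exact p = 1) nor Tfap4 (exact p = 0.413) changed. The deposited value does not separate transgene from endogenous Myc.

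**Figure D1:**
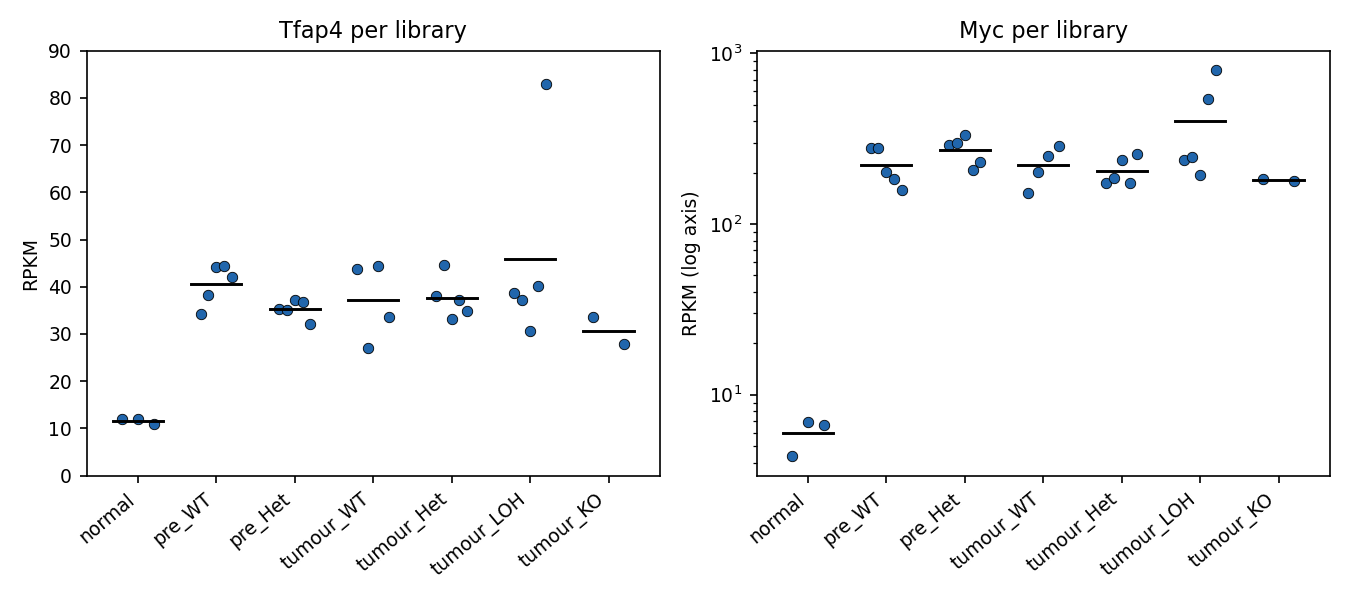
Tfap4 (linear axis) and Myc (log axis) in RPKM in each library (points) of the 7 groups, with group means as lines. Tfap4 had means of 11.6 in normal and 30.6 to 45.9 in all other groups, and in 1 LOH tumour it was 83.0.

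The effect of the EuMyc transgene was read from pre-tumour WT against normal cells. An age was recorded for the pre-tumour mice only, so a difference in age cannot be told apart from the transgene here. All 34 measured ribosome biogenesis genes rose, among them Nolc1, a nucleolar protein (126 ± 8.25 RPKM, SD, n = 5, against 23.3 ± 1.87, n = 3), and Polr1b, a subunit of RNA polymerase I (6.29-fold). Of 29 genes of nucleotide, polyamine and one-carbon synthesis 27 rose and 2 fell, and Srm, spermidine synthase, was 11.8-fold higher (95.2 ± 8.15 against 8.08 ± 1.82). Of 16 glycolysis genes 13 rose and 1 fell, with the hexokinase Hk2 at 14.5 ± 1.71 against 2.51 ± 0.443. Of 80 ribosomal protein genes 68 rose and 2 fell (68 and 3 adjusted over the list alone), with Rpl18a 3.14-fold higher. Of 35 genes of S phase and mitosis 21 rose, among them Ccne1, cyclin E1 (29.5 ± 1.02 against 13.8 ± 0.163), and the replication helicase gene Mcm4 (1.78-fold). The 4 largest rises after Myc and Srm included H2-Eb1, a class II MHC chain (195 ± 6.94 against 24.1 ± 4.17), and Gsto1, a glutathione transferase (9.29-fold).

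Genes of early B cells fell in the same comparison. Of 19 pro-B and pre-B genes 17 fell, including the recombinase gene Rag1 (log2 change -2.62 ± 0.06, SE), Igll1 of the surrogate light chain (14.7 ± 3.64 RPKM, SD, n = 5, against 164 ± 6.08, n = 3) and Dntt, which adds nucleotides at V(D)J joints (13.1 ± 3.63 against 185 ± 16.5). Of 18 stem and progenitor genes 13 fell and 1 rose (14 fell adjusted over the list alone), with Erg, an ETS factor of blood progenitors, at 2.24 ± 0.475 against 26.4 ± 2.59. Of 21 B-lineage identity genes 11 fell and 1 rose, with Ebf1, a factor that specifies B cells, at 42.4 ± 2.84 against 96.9 ± 5.56. The mature B list split into 8 that rose, such as Cd74, the invariant chain (4.20-fold), and 6 that fell, such as Cd38, an ectoenzyme (14.3 ± 1.32 against 87.3 ± 15.7), of 17. Among cell death genes of the Bcl2 family 2 of 9 rose and 6 fell, with Bid 3.14-fold higher and Bmf at 2.59 ± 0.465 against 40.5 ± 2.58. Of 9 cell-cycle inhibitors 2 rose and 5 fell, with Cdkn1b at 31.9 ± 5.43 against 102 ± 8.32, and of 17 p53 targets 8 rose and 6 fell (8 and 7 adjusted over the list alone), with Aen, a nuclease, 1.93-fold higher.

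Among markers of other cells falls were seen in the same comparison for 4 of 5 T cell genes (Lck, a T cell kinase, 3.68 ± 0.413 against 12.6 ± 1.97 RPKM, SD, n = 5 and 3), 6 of 6 NK genes (Gzma, a granzyme, 1.63 ± 0.582 against 7.41 ± 1.37) and 5 of 5 myeloid genes (Lyz2, lysozyme, 0.471 ± 0.132 against 4.83 ± 0.170). In the erythroid list 1 of 3 fell (Car2, a carbonic anhydrase), in the plasmacytoid dendritic list 1 of 2 (Spns3, a lipid transporter), and of 7 plasma cell genes 2 rose (Fkbp11, a folding enzyme, 8.31-fold) and 4 fell. Of 16 interferon-stimulated genes 15 fell, such as Stat1, the interferon signal transducer (3.83 ± 0.101 against 9.34 ± 1.14). Of 15 immediate-early genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), such as Jun, a subunit of AP-1 (35.3 ± 26.4 against 208 ± 61.8). The largest fall was that of Iglc2, a lambda light chain constant gene whose close copies may share its reads (1.26 ± 0.190 against 161 ± 7.81).

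Of 13151 genes tested between pre-tumour WT and normal cells, 3504 rose and 4506 fell, 8010 in all, and 2015 of these changed by 1 or more on the log2 scale. The balance depended on the scaling, with 3937 and 4080 after rescaling by median of ratios and 4201 and 3843 after quantile normalization. Camera called 11 of the lists, and 3 kept the call: ribosome biogenesis (adjusted p = 7.89e-20 and 0.0180 with an estimated correlation), pro-B and pre-B (6.94e-07 and 0.0180) and stem and progenitor (0.00142 and 0.0446). The call of nucleotide, polyamine and one-carbon genes (1.05e-12) was lost (adjusted p = 0.107 with an estimated correlation), as was that of glycolysis (1.51e-05; adjusted p = 0.116 with an estimated correlation). So it was for cell cycle (1.51e-05), interferon (1.40e-06), myeloid (0.00489) and B-lineage identity genes (0.0128), each at adjusted p = 0.179 with an estimated correlation. Ribosomal proteins (1.36e-14; adjusted p = 0.211 with an estimated correlation) and NK markers (0.0109; adjusted p = 0.218 with an estimated correlation) lost it too. For p53 targets the median change was negative (-0.22) while camera pointed up, without passing (adjusted p = 0.606). All normal libraries belonged to set B, and with only pre-tumour WT mice of the same number series 1 of 93 named genes lost its call.

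The loss of 1 Tfap4 copy before tumours was read from pre-tumour Het against pre-tumour WT cells. Erg, lower under the transgene, was 3.78-fold higher in Het (8.48 ± 2.89 RPKM, SD, n = 5, against 2.24 ± 0.475, n = 5). Of 19 pro-B and pre-B genes 6 rose, and 13 adjusted over the list alone, among them Smarca4, the ATPase of a chromatin remodelling complex (340 ± 16.5 against 242 ± 19.2), and Arpp21, a phosphoprotein gene (1.93 ± 0.275 against 0.576 ± 0.184). Of 17 mature B genes 8 fell and 3 rose (9 and 3 adjusted over the list alone). These included Ms4a1, which encodes CD20 (14.2 ± 1.93 against 35.6 ± 8.82), the class II genes Cd74 (346 ± 43.4 against 531 ± 43.7) and H2-Eb1 (115 ± 22.9 against 195 ± 6.94), and on the higher side Tnfrsf13c, the BAFF receptor (1.35-fold). The largest rise under the naming rule was Fcrl6, an Fc receptor-like gene (5.99 ± 2.13 against 0.627 ± 0.239), and Atp1b1, a sodium pump subunit, was 2.23-fold higher. Members of other lists that rose included Cdkn2a, a cell-cycle inhibitor (1.58-fold), Zmat3, a p53 target (2.09-fold), and Lat, a T cell adaptor (5.16 ± 0.989 against 1.94 ± 0.475), while Ccne1 fell to 0.807-fold. No B-lineage identity, NK, myeloid, erythroid, plasmacytoid dendritic, plasma cell, interferon or immediate-early gene passed. Adjusted over the list alone, both plasmacytoid dendritic genes rose, Cox6a2 and Spns3, and 1 rose and 1 fell in each of the plasma cell and B-lineage identity lists. On that count 4 of 9 Bcl2 family and 2 of 5 T cell genes rose, with 3 higher and 1 lower of 18 stem and progenitor genes and 2 higher and 2 lower of 9 cell-cycle inhibitors.

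In that comparison 347 of 13151 genes passed (198 rose and 149 fell), and 17 of them changed by 1 or more on the log2 scale. The split was 257 and 129 after rescaling by median of ratios and 221 and 135 after quantile normalization. Camera called the pro-B and pre-B list (median 0.44; adjusted p = 2.30e-10 and 0.00337 with an estimated correlation). The mature B (0.0159; adjusted p = 0.367 with an estimated correlation) and T cell lists (0.0136; adjusted p = 0.101 with an estimated correlation) lost the call, the former also without WT replicate 1, WT replicate 2 or Het replicate 4. Ribosomal proteins, of which none of 80 passed, were called lower (3.30e-06; adjusted p = 0.833 with an estimated correlation). The pre-tumour libraries came from 2 number series that coincide with sets A and B, with 2 WT and 3 Het libraries in A and 3 and 2 in B. Within each series all of the called genes kept their direction (337 of 337 and 339 of 339 genes tested), as is likely for genes called on the same libraries. Tested within a single series, 0 and 99 genes passed, in the same order. A term for series raised the count to 880. It was 4852 with library weights and 213 without the filter. The count was 225 without pre-tumour WT replicate 3, 173 without WT replicate 4, 159 without WT replicate 5, 214 without Het replicate 1 and 207 without Het replicate 3. In a fit of all 29 libraries no gene passed.

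Progression with WT Tfap4 was read from WT tumours against pre-tumour WT cells. Of the 4 WT tumours 3 lay in library set C, which held no pre-tumour library. Stage and library set can therefore hardly be told apart. The metallothionein gene Mt1 was 6.46-fold higher in tumours (212 ± 120 RPKM, SD, n = 4, against 32.9 ± 6.83, n = 5), and Emb, an adhesion glycoprotein gene, rose from 3.46 ± 0.738 to 29.6 ± 14.5. Pde5a, a cyclic GMP phosphodiesterase, fell from 3.83 ± 0.234 to 0.236 ± 0.323. Of 16 glycolysis genes 4 rose (10 adjusted over the list alone), among them the glucose transporter Slc2a1 (12.9 ± 2.52 against 8.46 ± 0.518). Of 35 cell cycle genes 8 fell (12 adjusted over the list alone), among them Mki67, a proliferation marker (113 ± 79.9 against 281 ± 30.1). Of 9 cell-cycle inhibitors 2 rose and 3 fell (2 and 5 adjusted over the list alone), with the retinoblastoma gene Rb1 at 6.07 ± 2.20 against 13.6 ± 1.19. Of 21 B-lineage identity genes 3 fell (4 adjusted over the list alone), with Ikzf1, a zinc finger factor of lymphocytes, at 74.7 ± 18.4 against 132 ± 13.2. Zap70, a T cell kinase, was the 1 of 5 T cell genes to rise (9.23 ± 8.88 against 1.51 ± 0.388). Of 7 plasma cell genes 1 rose (2 adjusted over the list alone), Mzb1, a chaperone of B and plasma cells (279.6 ± 129 against 142 ± 9.45), and 2 of the 4 tumours were sorted without the IgM gate. Of 14 immediate-early genes 2 fell, with Jun at 5.14 ± 3.57 against 35.3 ± 26.4, and of 2 plasmacytoid dendritic genes 1 fell, Spns3, at 1.46 ± 1.27 against 4.52 ± 0.937. Of 78 ribosomal protein genes 5 rose and 2 fell. The ribosome biogenesis gene Polr1b was 1.36-fold higher, the only 1 of 34 to rise, and none passed adjusted over the list alone. It lost its call without pre-tumour WT replicate 1, 2 or 5 or tumour WT replicate 1 or 3 (adjusted p = 0.0540 to 0.0784).

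The WT tumour comparison called 1339 of 12916 genes, of which 470 rose and 869 fell, and 355 changed by 1 or more on the log2 scale. The split was 598 and 727 after rescaling by median of ratios, and 657 and 794 after quantile normalization. All 7 list calls by camera were lost, with cell cycle and B-lineage identity genes lower and the others higher. The adjusted p values were 4.93e-06 for glycolysis (adjusted p = 0.107 with an estimated correlation), 1.16e-06 for cell cycle (adjusted p = 0.508 with an estimated correlation) and 0.0187 for T cell markers (adjusted p = 0.107 with an estimated correlation). B-lineage identity (0.0150) and plasma cell markers (0.0453) each had adjusted p = 0.350 with an estimated correlation, and ribosomal proteins (5.05e-04) and ribosome biogenesis (0.0378) each adjusted p = 0.682 with an estimated correlation. The mature B list had a negative median (-0.43) while camera pointed up, without passing (adjusted p = 0.970). With IgM- tumours alone, 2 WT and 2 Het in the fit, 3092 genes passed, and with a term for the library set 178. The fit shares a single spread per gene between stages, and many genes varied more in tumours (Mki67 SD 79.9 against 30.1). Leaving out tumours can lower that spread, so the higher count does not show a stronger difference. The count was 866 without pre-tumour WT replicate 1, 694 without replicate 3, 652 without replicate 4, 560 without replicate 5, 702 without tumour WT replicate 1 and 2347 without tumour WT replicate 4.

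Progression with 1 Tfap4 copy was read from Het tumours against pre-tumour Het cells. Of the 5 Het tumours 3 lay in library set C, without a pre-tumour library, so here too stage and library set are hard to tell apart. Rnase12, a ribonuclease family gene, had the largest rise (218 ± 214 RPKM, SD, n = 5, against 1.41 ± 0.471, n = 5), and Bok, a Bcl2 family member, was 16.3-fold higher (39.4 ± 7.66 against 2.42 ± 0.898). Rasgrp1, a Ras activator of lymphocytes, fell from 34.8 ± 7.68 to 0.703 ± 1.22, and Igkc, the kappa constant gene, fell from 966 ± 149 to 56.6 ± 51.6. Of 16 glycolysis genes 8 rose (12 adjusted over the list alone), with Pkm, a pyruvate kinase, 1.93-fold higher. Of 78 ribosomal protein genes 33 rose and 1 fell (46 and 2 adjusted over the list alone), with Rpl17 1.80-fold higher. Of 21 B-lineage identity genes 9 fell and 1 rose, with the ETS factor Spib at 43.7 ± 16.4 against 219.6 ± 18.2. Of 17 mature B genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), Ms4a1 from 14.2 ± 1.93 to 1.05 ± 0.804, while Cd22, an inhibitory receptor, was 2.02-fold higher. The pro-B and pre-B list split into 3 that rose and 5 that fell of 19 (5 and 5 adjusted over the list alone). Among them Vpreb2, a surrogate light chain gene with a close copy, was 10.5-fold higher and Il2ra, a pre-B surface receptor, fell from 1.99 ± 0.695 to 0.158 ± 0.146. Of 14 immediate-early genes 7 fell (8 fell and 2 rose adjusted over the list alone), with Fos at 8.12 ± 2.51 against 36.5 ± 24.0. Of 35 cell cycle genes 4 fell and 1 rose (none and 1 adjusted over the list alone), with the replication gene Gins2 1.71-fold higher. Zap70 rose here too (18.1 ± 6.75 against 1.85 ± 0.674), the myeloid integrin Itgam fell from 1.36 ± 0.137 to 0.157 ± 0.139, and both plasmacytoid dendritic genes fell, Spns3 from 6.26 ± 1.08 to 0.237 ± 0.111. Of these 5 tumours 3 were sorted on B220 alone.

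In Het cells 2994 of 12916 genes passed between stages (1513 rose and 1481 fell), and 808 changed by 1 or more on the log2 scale. With library weights 4923 passed, and the split was 1499 and 1555 after rescaling by median of ratios and 1715 and 1452 after quantile normalization. Camera called 6 lists, and all of the calls were lost with an estimated correlation. Higher were ribosomal proteins (3.15e-10; adjusted p = 0.541 with an estimated correlation) and glycolysis (6.73e-05; adjusted p = 0.272 with an estimated correlation). Lower were B-lineage identity (8.67e-05; adjusted p = 0.317 with an estimated correlation), immediate-early (0.00950) and mature B genes (0.0164), each at adjusted p = 0.541 with an estimated correlation, and cell cycle (0.0164; adjusted p = 0.771 with an estimated correlation).

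Whether the step from pre-tumour cell to tumour differed between Het and WT was asked of the interaction of stage and genotype. The change of Rnase12 in Het lay above that in WT (log2 difference 4.36 ± 0.61, SE; n = 5 and 5 pre-tumour cells, 5 Het and 4 WT tumours), as it did for Eng, a TGF-beta co-receptor (2.23 ± 0.38), and Vpreb2 of the pro-B and pre-B list (2.82 ± 0.31). It lay below that in WT for Igkc (-4.16 ± 0.51) and Adam19, a metalloprotease (-2.60 ± 0.37). In 2 of the genes named here both steps passed and had opposite directions. Vav3, an exchange factor for Rho GTPases (2.07 ± 0.24), rose in Het (log2 change 1.16) and fell in WT (-0.90), while Ly6a, the stem cell antigen Sca-1 (-2.19 ± 0.23), fell in Het (-1.03) and rose in WT (1.17). In all 58 of 12916 genes passed, 25 above and 33 below 0. No mature B gene of 17 passed (2 fell adjusted over the list alone), and the list's call (median -1.04, 4.84e-04) was lost (adjusted p = 0.600 with an estimated correlation). Plasma cell markers (0.0138; adjusted p = 0.600 with an estimated correlation), B-lineage identity (0.0138) and immediate-early genes (0.0129), each at adjusted p = 0.779 with an estimated correlation and each lower, lost it as well. So did ribosomal proteins (2.25e-04) and cell cycle genes (0.0306), higher, each at adjusted p = 0.883 with an estimated correlation. With IgM- tumours alone, 2 WT and 2 Het, 255 genes passed, and under the spread shared between stages this rise does not show a stronger difference. With a term for the library set 111 passed, with library weights 627, without the filter 27, and the count without a single library ran from 26 to 220. It was 38 without pre-tumour WT replicate 1, 28 without replicate 4, 26 without replicate 5, 29 without pre-tumour Het replicate 2 and 28 without Het replicate 3. Without tumour WT replicate 2 it was 220, without replicate 3 34 and without replicate 4 175, and it was 103 without tumour Het replicate 1 and 34 without replicate 4.

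The state of tumours with 1 Tfap4 copy was read from Het against WT tumours. Bok was 8.93-fold higher in Het (39.4 ± 7.66 RPKM, SD, n = 5, against 4.41 ± 4.50, n = 4), Eng was 8.41-fold higher (8.91 ± 2.70 against 1.06 ± 1.47), and Ifitm2, an interferon-induced membrane protein, was 42.3 ± 21.2 against 2.37 ± 2.28. Igkc was 56.6 ± 51.6 against 989 ± 401, Adam19 1.47 ± 0.945 against 16.7 ± 8.09 and Cebpb, a C/EBP factor of myeloid cells, 1.00 ± 0.745 against 7.38 ± 3.43. The pro-B and pre-B list had 1 of 18 that rose (3 adjusted over the list alone), Vpreb2 (12.8-fold), and camera called it (2.30e-04; adjusted p = 0.341 with an estimated correlation). Vpreb2 lost its call without tumour WT replicate 1 or 3 or Het replicate 3, 4 or 5 (adjusted p = 0.0502 to 0.0859). No mature B gene of 18 passed (2 fell adjusted over the list alone), and camera called the list lower (median -0.78, 2.01e-05; adjusted p = 0.269 with an estimated correlation). Plasma cell (0.00420) and immediate-early genes (0.00678), with no member that passed and 2 lower in each adjusted over the list alone, were called lower too, each at adjusted p = 0.269 with an estimated correlation. Cell cycle genes were called higher (0.0257; adjusted p = 0.819 with an estimated correlation) and, without tumour WT replicate 2, lower (0.00364). In all 67 of 13683 genes passed, 31 up and 36 down. In tumours of set C alone 5 passed, with library weights 458, in a fit of all 29 libraries 562, and the count was 190 without tumour WT replicate 2, 34 without WT replicate 3, 141 without WT replicate 4, 35 without Het replicate 3 and 35 without Het replicate 4.

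The state of tumours labelled LOH was read against WT tumours. Ap3b2, a vesicle adaptor subunit, was 11.4 ± 2.23 RPKM (SD, n = 5) against 0.0310 ± 0.0217 (n = 4), Rpl3l, a muscle paralogue of a ribosomal protein, 18.9 ± 8.42 against 0.159 ± 0.0841, and Cacna1h, a calcium channel, 20.3 ± 12.7 against 0.564 ± 0.947. Erg was 9.24-fold higher (log2 change 3.76 ± 0.73, SE). Of 18 pro-B and pre-B genes 4 rose (7 rose and 1 fell adjusted over the list alone), with Igll1 at 206 ± 93.5 against 11.2 ± 13.0. Of 18 mature B genes 3 fell (10 fell and 1 rose adjusted over the list alone), among them Ccr7, a homing receptor (5.55 ± 4.26 against 32.5 ± 12.5). Ly86, an immune receptor partner of B cells, was 1.37 ± 0.697 against 54.1 ± 7.96, and Adam19 was 0.895 ± 0.477 against 16.7 ± 8.09. Chd3, a helicase of a repressor complex, was 0.536 ± 0.366 against 26.0 ± 18.7. Impdh1, a guanine nucleotide synthesis enzyme, was the 1 of 29 in its list to rise (2 adjusted over the list alone; 92.5 ± 9.34 against 23.1 ± 15.0). Of 15 interferon-stimulated genes 2 rose, with the nucleic acid sensor Zbp1 at 3.72 ± 2.59 against 0.481 ± 0.599. Lat rose as 1 of 7 T cell genes (41.4 ± 28.9 against 4.12 ± 3.36), a call lost without tumour WT replicate 1 or 3 or LOH replicate 2 or 4 (adjusted p = 0.0564 to 0.0679), and 3 LOH and 2 WT tumours were sorted on B220 alone.

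Between LOH and WT tumours 371 of 13683 genes passed (195 rose and 176 fell), and 265 changed by 1 or more on the log2 scale. The camera calls of pro-B and pre-B (higher, 2.93e-04), mature B (median -1.43, 7.95e-06), interferon (higher, 5.11e-04) and immediate-early genes (lower, 0.0287) were lost, each at adjusted p = 0.540 with an estimated correlation. So were the higher calls of nucleotide synthesis (2.93e-04; adjusted p = 0.608 with an estimated correlation) and cell cycle genes (0.00506; adjusted p = 0.744 with an estimated correlation). In tumours of set C alone 63 genes passed, 58 of them shared, and those that kept their call there included Ap3b2, Rpl3l, Ly86, Chd3 and Adam19. With 3 and 3 libraries Erg went from a log2 change of 3.76 ± 0.73 (SE) to 4.29 ± 0.97 (adjusted p = 0.0921), Igll1 from 4.69 ± 0.72 to 4.47 ± 0.94 (0.0734), Impdh1 from 2.21 ± 0.36 to 2.28 ± 0.51 (0.0909) and Zbp1 from 1.61 ± 0.30 to 1.62 ± 0.42 (0.145). These calls ended with fewer libraries and a larger SE, not a fold far from the first. Ccr7 went from -2.59 ± 0.47 to -2.06 ± 0.39 (0.0564), a smaller change. The count was 189 without tumour WT replicate 3, 236 without LOH replicate 2, 223 without LOH replicate 4, 243 without the filter, 567 with library weights and 1429 in a fit of all 29 libraries.

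The same question was asked of KO against WT tumours, with 2 KO libraries. Ap3b2 (10.9 ± 2.58 RPKM, SD, n = 2, against 0.0310 ± 0.0217, n = 4), Rpl3l (18.5 ± 9.54 against 0.159 ± 0.0841) and Fn1, the matrix protein fibronectin (7.86 ± 0.128 against 0.0310 ± 0.00942), were higher in KO. Agpat4, a phospholipid acyltransferase, was 0.688 ± 0.170 against 5.11 ± 1.07. Only these 4 of 20 named genes kept their call without each library in turn. Without a KO library 1 remains, and the spread then comes from the other groups. Without each WT tumour in turn 10 of the 20 kept it. Of 18 pro-B and pre-B genes 1 rose, and 7 adjusted over the list alone, with Vpreb2 26.0-fold higher. No mature B gene of 18 passed, and 2 fell adjusted over the list alone. In all 54 of 13683 genes passed, 42 up and 12 down, and 9 lists were called by camera, all lost, with mature B and immediate-early genes lower and the other 7 higher. The mature B list (median -1.12, 1.60e-06), interferon (1.22e-06) and immediate-early genes (0.00159) were each at adjusted p = 0.215 with an estimated correlation, and pro-B and pre-B genes (3.15e-05) and p53 targets (3.15e-05) each at adjusted p = 0.265 with an estimated correlation. Nucleotide synthesis (2.99e-06) and glycolysis (0.00212) were each at adjusted p = 0.302 with an estimated correlation, erythroid markers (0.00212) at adjusted p = 0.439 with an estimated correlation, and cell cycle genes (3.15e-05) at adjusted p = 0.619 with an estimated correlation. In set C alone 19 genes passed, with library weights 652, in a fit of all 29 libraries 394, and the count was 86 without tumour WT replicate 1, 102 without WT replicate 2, 34 without WT replicate 3, 24 without KO replicate 1 and 10 without KO replicate 2.

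Of the 54 genes called in KO tumours 50 were called in LOH tumours in the same direction, 38 up (0.599 expected) and 12 down (0.154 expected), and none in the opposite direction. Both comparisons used the same 4 WT tumours. When these were divided 2 and 2 in all 6 ways, the shared genes numbered 22 up on average (16 to 30) and 6.67 down (3 to 9). The covariance of the log2 changes was 0.208 with shared controls and 0.125 on average with divided ones (0.0880 to 0.156). In 100 simulations with shared controls and no shared change its mean was 0.0590 (highest 0.0671), to be set beside 0.208 only. Genes were drawn independently there, so that range leaves out genes that vary together and may be too narrow. Ap3b2, Rpl3l, Fn1, Steap4, a metalloreductase, and Uaca, a coiled-coil protein, were among the shared genes that rose, and Ly86, Chd3 and Adam19 among those that fell.

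**Figure D2:**
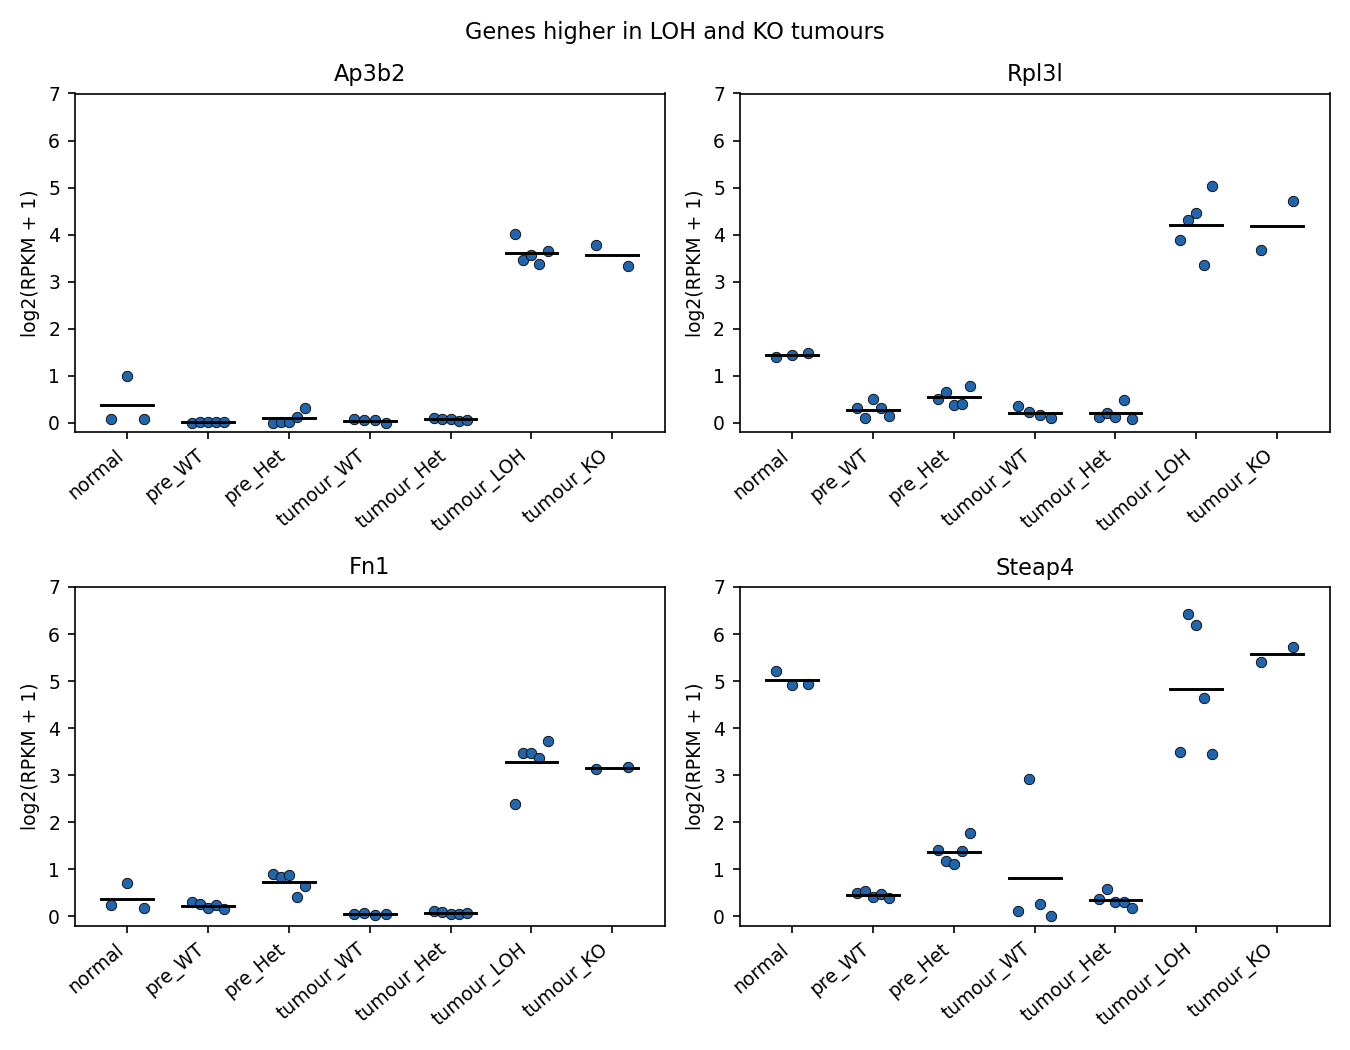
Values of Ap3b2, Rpl3l, Fn1 and Steap4 as log2(RPKM + 1) in each library (points) of the 7 groups, and lines at the mean of each group. Mean Ap3b2 was 0.0310 RPKM in WT, 0.0471 in Het, 11.4 in LOH and 10.9 in KO tumours.

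The label LOH was also read against Het tumours. Ap3b2 (11.4 ± 2.23 RPKM, SD, n = 5, against 0.0471 ± 0.0220, n = 5), Rpl3l (18.9 ± 8.42 against 0.162 ± 0.139) and Fn1 (9.19 ± 2.98 against 0.0520 ± 0.0184) were higher in LOH. Prkch, a protein kinase C isoform, was 13.2 ± 7.74 against 0.236 ± 0.177, and Grn, the growth factor progranulin, 31.8 ± 6.24 against 4.11 ± 1.80. Etv5, an ETS factor downstream of ERK signals, was 0.124 ± 0.0412 against 18.5 ± 5.09, and Spred1, an inhibitor of the Ras pathway, 0.102 ± 0.0398 against 23.4 ± 13.3. Rnase12 was 3.40 ± 3.25 against 218 ± 214. Of 15 interferon-stimulated genes 3 rose (7 adjusted over the list alone), with Zbp1 at 3.72 ± 2.59 against 0.110 ± 0.0550. Of 18 mature B genes 2 fell (3 adjusted over the list alone), with Cd22 at 0.339-fold. Of 21 B-lineage identity genes 2 rose, and Spib (2.51-fold) lost its call without Het replicate 1, 3 or 4 or LOH replicate 1, 2, 3 or 4 (adjusted p = 0.0539 to 0.0827). Of 16 stem and progenitor genes 3 fell, and the ETS factor Fli1 (30.9 ± 7.10 against 53.9 ± 4.96) lost its call without Het replicate 3 or 4 or LOH replicate 5 (0.0515 to 0.0706). Of 8 plasma cell genes 1 rose (2 adjusted over the list alone), Mzb1 (2.21-fold), which lost its call without Het replicate 3 or 4 (0.0502 to 0.0523).

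Between LOH and Het tumours 280 of 13683 genes passed (144 rose and 136 fell), and 197 changed by 1 or more on the log2 scale. Of the camera calls, all of them higher except that of ribosomal proteins, interferon (2.61e-07) and plasma cell genes (0.00964) were lost, each at adjusted p = 0.493 with an estimated correlation. Ribosomal proteins (0.00287), nucleotide synthesis (0.00964), myeloid (0.00964) and ribosome biogenesis genes (0.0154) were lost too, each at adjusted p = 0.861 with an estimated correlation. In tumours of set C alone 42 genes passed, 41 of them shared, among them Ap3b2, Rpl3l, Fn1 and Prkch. With 3 and 3 libraries Etv5 went from a log2 change of -4.08 ± 0.62 (SE) to -4.26 ± 0.84 (adjusted p = 0.0846), Spred1 from -4.34 ± 0.61 to -4.46 ± 0.88 (0.0846), Zbp1 from 1.96 ± 0.28 to 2.08 ± 0.42 (0.0916) and Cd22 from -1.52 ± 0.29 to -1.51 ± 0.41 (0.245). In these genes the log2 change stayed near the first, while the SE grew with fewer libraries. In others the change shrank as well. Fli1 went from -0.81 ± 0.17 to -0.52 ± 0.19 (adjusted p = 0.411), Mt2 from 4.27 ± 0.70 to 3.40 ± 0.91 (0.240) and Klra1 from -4.29 ± 0.80 to -3.66 ± 1.14 (0.315). The count was 152 without Het replicate 3, 157 without Het replicate 4, 182 without LOH replicate 2, 462 with library weights and 1070 in a fit of all 29 libraries.

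**Figure D3:**
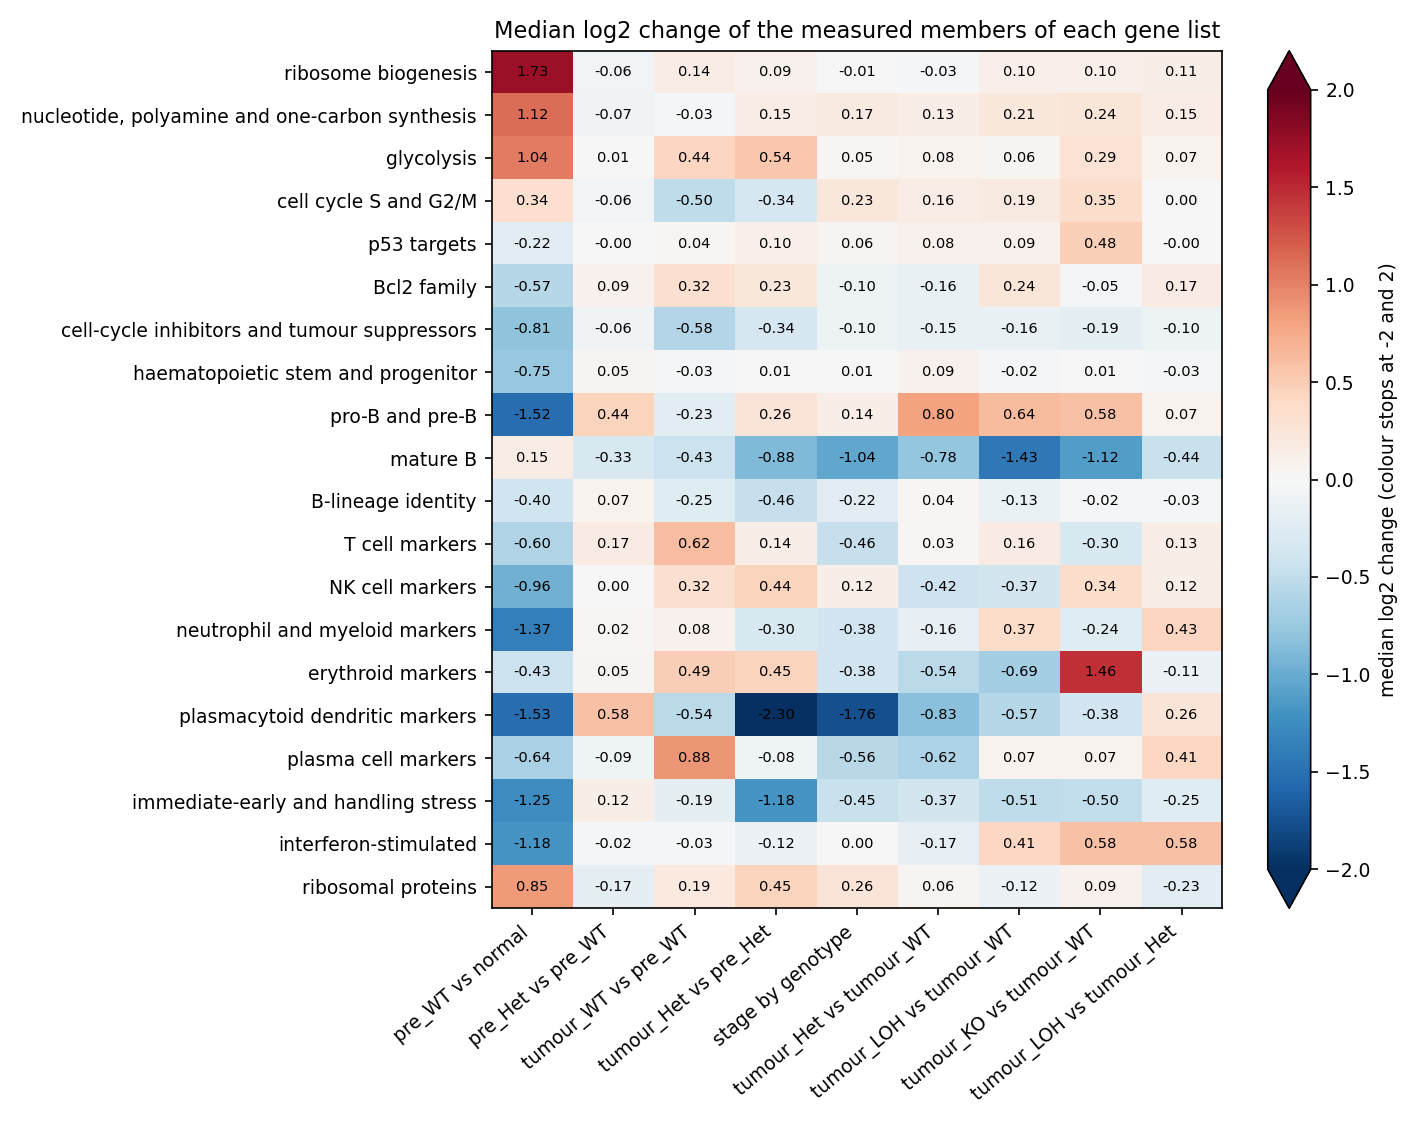
Median log2 change of the members of the 20 gene lists (vertical) in the 9 comparisons (horizontal), with a colour scale that stops at -2 and 2. The pro-B and pre-B list had a median of -1.52 in pre-tumour WT against normal cells, 0.44 in pre-tumour Het against WT and 0.64 in LOH against WT tumours.

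In some lists without a call the median of the members and the direction of camera had opposite signs. In pre-tumour Het against WT cells the cell-cycle inhibitors had a median of -0.06 and pointed up, and so, next to 0, did the p53 targets. In WT tumours against pre-tumour cells this held for nucleotide synthesis (-0.03) and stem and progenitor genes (-0.03), both up, and in the interaction for stem and progenitor genes (0.01) and, next to 0, interferon genes, both down. In Het against WT tumours it held for Bcl2 family (-0.16, up), B-lineage identity (0.04, down) and T cell genes (0.03, down), and in LOH against WT tumours for stem and progenitor genes (-0.02, up). In KO against WT tumours Bcl2 family (-0.05, up), T cell (-0.30, up), plasmacytoid dendritic (-0.38, up) and plasma cell genes (0.07, down) did so. In LOH against Het tumours B-lineage identity (-0.03, up), NK (0.12, down), immediate-early (-0.25, up) and, next to 0, p53 target genes (up) did.

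Whether the genes of pre-tumour Het cells moved alike in tumours was asked of 342 called genes that were also tested in tumours. In LOH against WT tumours 308 of them (90.1%) had the same direction, 170 of 194 higher and 138 of 148 lower, while 61.2% of all genes tested in both comparisons did. Called in both were 42 higher genes (2.37 expected), with Erg, Steap4 and Uaca, and 32 lower genes (1.95 expected), with Ly86. In KO against WT tumours 308 had the same direction (50.1% of all genes), with 14 called up in both (0.523 expected) and 4 down (0.141 expected). In Het against WT tumours 262 did (76.6%, against 48.7% of all genes), with 3 called up (0.339 expected) and 8 down (0.423 expected). The LOH, KO and Het comparisons shared the same WT tumours, so their agreements are not independent of each other. Among 100 divisions of the LOH and WT tumours the real labels gave the highest number, but 307 came from a division in which a single LOH and a single WT tumour changed places, and the median was 165. For Het and WT tumours 6 of 100 divisions gave as many as the real 262, the highest other 272, so chance is not excluded there, and for KO the 15 divisions (highest other 276) were too few.

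**Figure D4:**
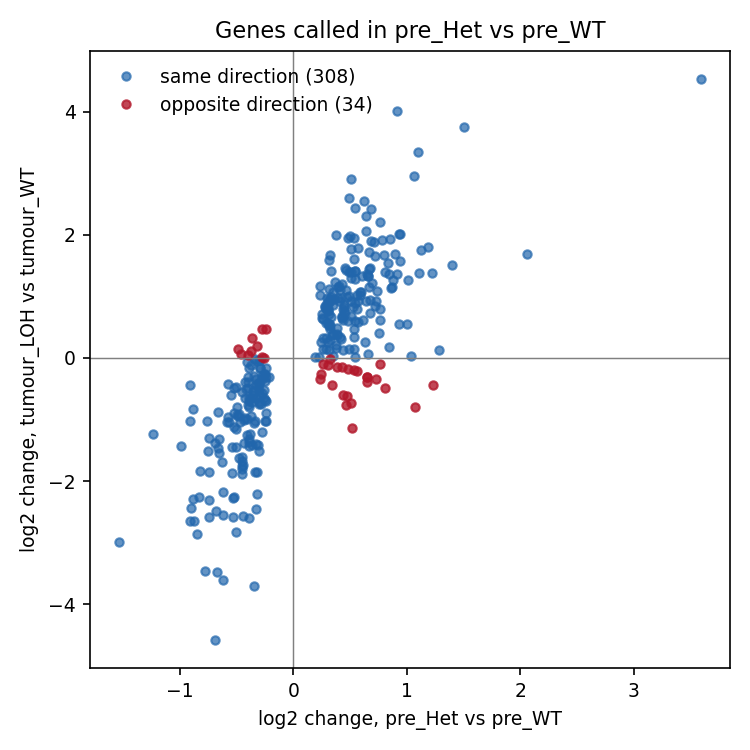
Log2 change in pre-tumour Het against WT cells (horizontal) and in LOH against WT tumours (vertical), both on log2(RPKM + 1), for 342 genes called in the former (points). The 308 points with the same direction in both lie in the lower left and upper right.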

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

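The tests of explanations in this section were chosen after the results had been seen, except that of the scale of the whole library, while the interaction and the leaving out of single libraries were planned. Of 300 gene and group sets of 4 or 5 libraries from 117 named genes, 19 held a library past Dixon's critical value at 95%, where 15 would be past it by chance, about 1 in 20 groups.

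The first pattern is the set of genes that differed between pre-tumour Het and WT cells, with Erg higher and Ms4a1 lower, and the first question is whether any split of the same 10 libraries does as well. Of 100 splits 2 called as many genes, the real one with 347 and 1 with 5020, and the latter divides the libraries by number series and library set and not by chance. With a term for the series the real labels called 880 genes, and 1 of 100 splits reached that, the highest other giving 2. An unequal share of the series is therefore not likely the source. That 100% of the called genes kept their direction within each series adds little, as they were called on these same libraries. Normal-like cells mixed into the Het libraries were tested by the 10 genes that fell most from normal to pre-tumour WT cells, which allow a share of 8.13% at most (median 0.430%), against a median of 30.8% (IQR 18.7 to 61.7) needed by the 157 of 198 higher genes that had fallen and 25.8% for Erg. The 157 genes were called for being higher in Het, which favours large shares, while the 10 were not chosen on the Het values. That the 10 lay below the median was thus close to fixed by the choice. They still cap the share of cells that carry them at normal levels. Cells of a single earlier stage without those 10 genes may still add to the pattern, and so may a slower loss of the early genes.

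The next pattern is that Tfap4 stayed high in tumours labelled LOH (45.9 RPKM) and KO (30.6), against 37.2 in WT tumours. The LOH mean rests on replicate 5, and the KO mean lay below that of WT (0.825-fold), where 2 libraries could not pass (smallest exact p = 0.133). Exchanged labels are 1 explanation, and 11 genes, among them Ap3b2, Rpl3l and Fn1, separated LOH and KO from WT and Het tumours by a gap of 1 on the log2 scale, while the highest of the other splits (100 in all) gave 0, so exchange of libraries is not likely. A deletion that leaves most of the transcript in place could give the same values, and the deleted part is not known here. Cells like the normal or pre-tumour libraries would have to make up 68.4% to 204% of a tumour library to give all of its Tfap4. In each of the 7 libraries all 10 abundant genes tested stayed below the share needed there (at most 59.8% of it). These 10 had the lowest mean share in these same libraries among 2482 candidates, so that outcome was close to fixed by the choice. Each still caps the share of such cells, if these kept their levels, and Rasgrp1 allows 5.46% at most. Only under that condition are such cells too few to give all Tfap4 reads. A small part from such cells is not excluded. Blk allows 18.0% at most, and the highest value of any gene, 56.8% for Fosb in a single library, missed a stricter bound of 0.5 of the lowest share needed. The stricter bound came first, the other was added after the shares were seen, and unnamed genes such as Gm10800 were taken out of the 10 after a first run. Cells of other kinds were not tested.

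The last of the 3 patterns is LOH tumour replicate 5, with Tfap4 at 83.0 RPKM (Dixon 0.732, others 30.6 to 40.1) and Myc at 799 RPKM. The log2 excess over the other LOH tumours was 1.17 for Tfap4 and 1.51 for Myc. The 20 nearest genes had a median excess of -0.21 (IQR -0.48 to 0.14) around Tfap4 and 0.0918 (-0.21 to 0.44) around Myc. A gain that spans most of these neighbours is thus not likely. A gain of the gene alone or of the transgene would not show in them. The whole library was not scaled up either, as the median over all genes was -0.0621. LOH replicate 4 also had high Myc (539 RPKM), with Tfap4 at 40.1, so high Myc did not go with high Tfap4 there. These were the 2 LOH tumours of library set A and of their number series, in which pre-tumour Myc was higher too (279 to 335 RPKM against 158 to 232). The other tumours of that series, WT replicate 1 (153) and Het replicate 5 (256), did not have Myc as high. What raised Myc or Tfap4 stays open, and a transgene with more copies was not tested.

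Splits of the labels were also counted for the other comparisons. For pre-tumour WT against normal cells 1 of 56 splits called as many genes (8010; highest other 240), for WT tumours against pre-tumour cells 1 of 100 (1339; highest other 0) and for Het tumours against pre-tumour cells 1 of 100 (2994; highest other 940). Het against WT tumours gave 1 of 100 (67; highest other 18), LOH against WT 1 of 100 (371; highest other 218) and LOH against Het 1 of 100 (280; highest other 1). For the same direction in pre-tumour Het cells and LOH tumours it was 1 of 100 (308; highest other 307). For pre-tumour Het cells and Het tumours 6 of 100 splits did as well (262; highest other 272), so chance may explain it, and for KO tumours the 15 splits were too few (308; highest other 276). For the interaction of stage and genotype 2 of 100 splits called as many genes (58; highest other 726), and the other one kept the tumour labels and divided the pre-tumour mice by series.

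The stages differed between Het and WT for 58 genes by that interaction. The named ones above 0 were Rnase12 (4.36), Scn4b (3.35), Ifitm2 (3.04), Bok (2.88), Vpreb2 (2.82), Adgrg1 (2.55), Eng (2.23), Vav3 (2.07), Rnase11 (2.06) and Kif13a (1.99). Those below 0 were Pou2f2 (-1.32), Tubb2b (-1.57), Myo1e (-1.65), Zfp516 (-1.66), Mctp2 (-1.86), Zbtb7b (-1.93), Grn (-2.11), Ly6a (-2.19), Rassf4 (-2.41), Adam19 (-2.60) and Igkc (-4.16). Of these 21 genes 7 lost their call without single libraries of the 19: Bok without 7 of them (adjusted p up to 0.0574), Adgrg1 11 (0.0630), Pou2f2 14 (0.106), Zfp516 4 (0.0538), Mctp2 8 (0.0630), Zbtb7b 13 (0.0839) and Grn 8 (0.0630).

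WT tumour replicate 2 stood apart as a whole, with a correlation of 0.876 to 0.899 with the other WT tumours, against 0.931 to 0.958 among these, and single WT tumours stood apart for several genes. Replicate 1 was high for Capn2 (Dixon 0.975; 21.9 RPKM, others 6.87 to 7.09) and Cacna1h (0.968; 1.98, others 0.0741 to 0.110) and low for Blvrb (0.839; 10.4, others 54.2 to 73.8). Replicate 2 was high for Steap4 (0.911; 6.50, others 0 to 0.197) and Fam169b (0.834; 68.9, others 2.85 to 5.22). Replicate 3 was low for Emb (0.938; 7.92, others 34.6 to 38.0) and high for Col5a3 (0.940; 5.73, others 0.157 to 0.287) and Hook1 (0.924; 1.53, others 0.0261 to 0.0986).

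Among other tumours Het replicate 1 was high for H19 (0.797; 1455 RPKM, others 6.90 to 21.8) and low for Chd3 (0.816; 2.57, others 20.2 to 30.7), and Het replicate 2 was high for Rasgrp1 (0.893; 2.88, others 0.0555 to 0.213) and Brwd1 (0.758; 1.54, others 0.174 to 0.415). LOH replicate 3 was high for Gimap4 (0.823; 34.7, others 0.695 to 1.90), and LOH replicate 1 was low for Fn1 (0.734; 4.23, others 9.35 to 12.3). Before tumours, WT replicate 2 was low for H2-Eb1 (0.918; 183, others 198 to 199), WT replicate 4 for Ly6a (0.725; 0.834, others 1.25 to 1.43), Het replicate 2 for Tmem121 (0.752; 0.165, others 0.270 to 0.306) and Het replicate 5 for Vpreb2 (0.715; 0.517, others 1.23 to 1.60).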

How the results depend on the processing

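Settings were planned except those of the library set, labels exchanged within the mouse number series and, for the gene lists, those beyond the pseudocount, median of ratios and estimated correlation, which were added after the data were seen. In most settings results were the same: of the settings of named genes 6011 were the same, 857 weaker, 2 stronger and none reversed. The losses of named calls were uneven. In set C alone 74 of 104 were lost, and with a term for the library set 80 of 253. Without the filter 80 of 379 were lost, and in a fit of all 29 libraries 53 of 379. Median of ratios lost 6 of 379 and quantile normalization 14 of 379. A single list result was reversed, in a setting added later, cell cycle genes in Het against WT tumours, which camera called higher and, without tumour WT replicate 2, lower (adjusted p = 0.00364, and from 1.68e-05 to 0.106 without each library in turn).

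For gene counts, a minimum log2 change of 1 left 2015 of 8010 genes in pre-tumour WT against normal, 17 of 347 in pre-tumour Het against WT, 355 of 1339 in WT tumours and 808 of 2994 in Het tumours against pre-tumour cells. Without the filter counts fell to 213 (pre-tumour Het against WT), 27 (stage by genotype) and 243 (LOH against WT). A fit of all 29 libraries gave 0 for pre-tumour Het against WT, and 562 (Het), 1429 (LOH) and 394 (KO) against WT tumours and 1070 for LOH against Het. Library weights gave 4852 for pre-tumour Het against WT, 4923 for Het tumours against pre-tumour cells, 627 for stage by genotype, 458 (Het), 567 (LOH) and 652 (KO) against WT tumours and 462 for LOH against Het. The series term gave 880 for pre-tumour Het against WT. With IgM- tumours alone, 2 WT and 2 Het, counts were 3092 for WT tumours against pre-tumour cells and 255 for stage by genotype. Added later, the term for the library set gave 178 for WT tumours against pre-tumour cells and 111 for stage by genotype, and set C alone gave 5 (Het), 63 (LOH) and 19 (KO) against WT tumours and 42 for LOH against Het.

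Without each library in turn, counts ran from 6813 to 7824 (pre-tumour WT against normal), 159 to 472 (pre-tumour Het against WT), 560 to 2347 (WT tumours against pre-tumour cells), 2101 to 3419 (Het tumours against pre-tumour cells), 26 to 220 (stage by genotype), 34 to 190 (Het against WT tumours), 189 to 367 (LOH against WT), 10 to 102 (KO against WT) and 152 to 218 (LOH against Het). Log2 changes of Tfap4 ran from 1.67 to 1.78 and of Myc from 4.79 to 5.08 in pre-tumour WT against normal, weaker only as fewer libraries could not reach exact p = 0.05. Tfap4 ran from -0.25 to -0.16 in pre-tumour Het against WT (exact p = 0.0159 without WT replicate 1), and by median of ratios it was -0.17 (exact p = 0.0397). With labels exchanged within the mouse number series Myc was 0.21 higher in pre-tumour Het than WT (exact p = 0.02). Myc ran from -0.50 to -0.32 in Het tumours against pre-tumour Het, passing at -0.48 without tumour Het replicate 5 and at -0.50 without pre-tumour Het replicate 4. Myc in LOH against Het tumours ran from 0.46 to 0.97, with 0.85 without Het replicate 5 (exact p = 0.0317), and by median of ratios it was 0.82 (exact p = 0.0476).

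With an estimated correlation the lists called by camera fell from 11 to 3 (pre-tumour WT against normal) and from 4 to 1 (pre-tumour Het against WT). From 7, 6, 6, 5, 6, 9 and 6 they fell to 0 in the other comparisons. WT tumours against pre-tumour cells had 470 up and 869 down as deposited, 598 and 727 by median of ratios and 657 and 794 by quantile normalization. The larger side changed in pre-tumour WT against normal (4201 up and 3843 down by quantile normalization), in Het tumours against pre-tumour cells (1499 and 1555 by median of ratios) and in Het against WT tumours (36 and 30 by quantile normalization). Quantile normalization moved the median of all genes from -0.08 to 0.03 in pre-tumour WT against normal. In every case the cause was not tested.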

Other observations

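The genes in this section that lie outside the naming rule were chosen after their values were seen. Some genes that fell under the transgene, Steap4 and Erg, were higher in KO tumours than in pre-tumour WT cells. Steap4, a metalloreductase gene, had 31.6 RPKM in normal cells, 0.371 in pre-tumour WT, 1.61 ± 0.498 (SD, n = 5) in pre-tumour Het, 40.1 ± 35.6 in LOH (n = 5) and 46.8 ± 7.42 in KO tumours (n = 2), with 0.273 in Het tumours. Erg, an ETS factor, went from 26.4 in normal to 2.24 in pre-tumour WT and 8.48 in pre-tumour Het cells. In tumours it was 7.57 ± 9.21 in WT, 28.2 ± 16.5 in Het, 69.95 ± 34.97 in LOH and 85.7 ± 17.5 in KO. The mean of Erg in Het tumours (10.9 to 49.9) thus lay near that of normal cells, unlike that of Steap4. Of the genes higher in LOH than in WT tumours 66.2% (102 of 154 tested in both) had fallen from normal to pre-tumour WT cells, against a median of 35.1% in 10000 random lists (upper end of the central 95% 42.9%). Of the genes lower in LOH 47.0% (78 of 166) had fallen as well, above the 42.2% of random lists, so earlier falls were frequent on both sides. The return of lost genes may be part of what separates the groups and cannot be all of it. A return itself was not tested, as LOH tumours were not compared with normal or pre-tumour WT cells.

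Etv5, an ETS factor that ERK signals induce, was at least 14.1 RPKM in all 5 Het tumours and 17.6 in WT tumour replicate 4, was high in WT tumour replicate 2 as well, and was at most 0.665 in every other tumour. Spred1, a Ras pathway inhibitor, followed it with 14.6 to 46.7 in Het, 20.2 and 12.5 in the same WT tumours and 0.102 ± 0.0398 (SD, n = 5) in LOH. Dusp6, an ERK phosphatase, was 124 to 187 in Het, 283 and 92.3 in those WT tumours, 2.17 and 5.01 in the others and 5.83 to 34.0 in LOH. A list of ERK output genes was written down after Etv5, Etv4, Spry2, Spry4 and Dusp6 had been seen. Only Etv5 was left out of its mean, so the 9 genes averaged still held the other genes already seen. Their mean log2 value was 3.42 ± 0.462 in Het (3.05 to 4.14) and 1.71 ± 0.323 in LOH tumours (1.34 to 2.08; exact p = 0.00794, adjusted over 5 comparisons 0.0198). It was 1.48 ± 0.145 in pre-tumour Het cells (exact p = 0.00794), 2.25 ± 1.22 in WT and 1.65 ± 0.231 in KO tumours, without a difference from WT for Het (exact p = 0.127), LOH (0.333) or KO (0.800). Higher ERK output in Het than in LOH tumours is consistent with these values, and since the list was written after the genes were seen, it is not an independent test.

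Single tumours differed in other genes. H19, an imprinted non-coding gene, was 1455 RPKM in Het tumour replicate 1, and its neighbour Igf2, a growth factor, was 56.1 there and at most 0.156 in other Het tumours. Cdkn2a, a cell-cycle inhibitor often lost in EuMyc tumours, was 90.8 RPKM in WT tumour replicate 2 and 1.70 to 15.6 in all other tumours. The same tumour had 99.9 RPKM of Iglc2, the lambda constant gene, where normal cells had 161 ± 7.81 (SD, n = 3). Its Bcl2, a survival gene, was 14.8, against 2.97 in WT replicate 4, 3.10 to 4.59 in Het and 0.449 to 1.05 in LOH tumours. Igkc, the kappa constant gene, was 715 to 1584 RPKM in WT, 25.6 to 148 in Het, 39.3 to 431 in LOH and 57.0 to 134 in KO tumours.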
